A study of Mus musculus with 23 samples.

How the data were processed

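RNA was measured in tissue punches of the nucleus accumbens of 23 mice, taken 1 h after saline or cocaine at 15 mg/kg, with 1 array per animal. Per the labels, total RNA was isolated with the mirVana kit, labelled as biotin-cRNA with the Illumina TotalPrep-96 kit and hybridised to MouseWG-6 v2 arrays. The deposited raw table holds the intensity of each probe on each array, which per the file headers is non-normalized. Between 24.9% and 30.3% of its values on each array are below 0, so the background had been subtracted before the authors deposited it, by a step not given in the sources used here. Beside each intensity the deposited table holds a detection p-value, which per the file headers belongs to the same array, and whose steps show ranks among negative-control beads. The authors' processed values are on a log2 scale and quantile normalized between arrays, which was read from the deposited values, since every array holds the same sorted values. The software behind them is not given in the sources used here. They cover the probes of 9274 genes and are null for the other probes.

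The columns of the raw table name the genotype, the injection and an array number (1 to 24, with 8 absent) but not the animal. Its arrays were therefore grouped by genotype and injection only, and no sex term was fitted to them, although a sex term had been planned. Sex was tested in the authors' processed values, whose labels give the sex and a replicate number of each animal. Group means of the authors' values and of the log2 raw intensities, not normalized and with a floor of 16, correlated with r = 0.999988 to 0.999996 across probes, which are not independent replicates. The median difference, authors' values minus raw, was -0.02 in wild-type saline, -0.05 in wild-type cocaine, 0.17 in heterozygous saline and -0.07 in heterozygous cocaine arrays.

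The raw intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3. The negative-control moments were inferred from the detection p-values, and an offset of 16 was added. Probes with a detection p under 0.01 on at least 5 arrays were kept (18509 probes). Genes were taken from the annotation table of the array, in which 34885 probes have 1 gene, 18 several and 10378 none. Of the probes tested 2645 had no single gene and entered the adjustment only. Each of the 10138 genes was represented by its tested probe with the highest mean log2 intensity. The number of arrays limits the precision.

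A linear model of 4 groups was fitted with limma to all 23 arrays (19 residual degrees of freedom), with empirical Bayes moderation and two-sided moderated tests. The comparisons were of cocaine against saline (averaged over genotypes, in wild type and in heterozygotes), of heterozygotes against wild type (averaged over injections, after saline and after cocaine) and their interaction. The sex comparison, averaged over the 4 groups, and the interaction of sex and cocaine were fitted in the same way to the authors' values. The p-values were adjusted by Benjamini-Hochberg over all probes tested in a comparison, and a gene was called at an adjusted p under 0.05. Where a gene was undetected on all arrays of the lower group, its fold change was bounded with the detection floor of those arrays and written as at least that fold. Foxp2 was also tested probe by probe within each injection with an exact permutation test, two-sided, with adjustment over 6 tests.

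Before the data were examined, 26 gene lists were fixed. They comprised immediate-early transcription factors, activity-regulated effector genes, MAP kinase feedback genes, glucocorticoid-responsive, circadian, heat shock and endoplasmic reticulum stress genes, transmitter receptors, neuropeptides and opioid receptors, reported Foxp2-linked genes, the FOXP family, the mitochondrial respiratory chain, sex-linked genes, and markers of 13 cell types. Each list was tested with camera of limma at a preset correlation of 0.01, with adjustment over the 26 lists of a comparison, and beside it with an estimated correlation and with fry. Scores of a list are the mean over its measured genes of the log2 deviation from the mean of all arrays. The rule for named genes was also fixed before the data were examined. It takes the 10 called genes with the largest increase and the 10 with the largest decrease, up to 4 called members with the smallest p of each list, and the 3 genes with the smallest p where 0 genes were called. Foxp1, Foxp2 and Foxp4 were named in each genotype comparison.

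The alternatives planned before the data were examined were quantile normalization without background correction, an offset of 50, the authors' values, no filter, detection on all 23 arrays, a replicate block, array weights, an intensity trend with robust moderation, fits of the compared groups alone, all probes counted, single sexes, and leaving out each array. Added after the data were seen were blocks of 6 array numbers, the excitatory marker score as a covariate, the striatal score as a covariate for Foxp2, the authors' values without sex, and fits without the 3 arrays that stand apart on the first principal component. The other splits of the arrays numbered 100 per comparison, drawn with a fixed seed. The procedure was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 log2 unit in each comparison. A slide block was not used here, since no slide is named, and whether probes overlap the mutated base was not analysed here.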

Results

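Gene expression was measured in tissue punches of the nucleus accumbens, the ventral part of the striatum, of C57BL6 mice. The animals were killed 1 h after an intraperitoneal injection of saline or of cocaine at 15 mg/kg, a psychostimulant that blocks the reuptake of dopamine. They were wild-type or carried a premature stop codon in 1 copy of Foxp2, a forkhead transcription factor expressed in the striatum. Total RNA of each animal was hybridised to an Illumina MouseWG-6 v2 bead array, which gives a fluorescence intensity for each probe. The 23 arrays comprised 6 of wild-type mice given saline, 6 of wild-type mice given cocaine, 5 of heterozygotes given saline and 6 of heterozygotes given cocaine. Between 16102 and 17933 probes were detected per array, the median intensity lay between 15.9 and 33.4 units, and pairs of arrays correlated with r between 0.967 and 0.991 over the probes tested. The number of arrays limits the precision. After filtering, 18509 probes were tested, and 10138 genes were each represented by 1 of them.

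The first comparison was of the mutated gene itself, as a check of the genotype labels. Foxp2 was lower in heterozygotes than in wild type after saline. Its 3 detected probes stood at 65.7%, 68.2% and 71.5% of the wild-type level (5 against 6 arrays). The means were 8.45 ± 0.09 against 9.05 ± 0.13, 8.18 ± 0.21 against 8.73 ± 0.27 and 8.61 ± 0.20 against 9.09 ± 0.12 (log2 intensity, SD). In the first and last of these probes all 5 heterozygous arrays lay below all 6 wild-type arrays, and in the other 4 of 5 did. Two-sided exact permutation tests gave p = 0.00216, 0.00866 and 0.00216, where 0.00216 is the smallest that 462 splits can give. Adjusted over the 6 tests of this family these became 0.00649, 0.0173 and 0.00649. After cocaine the 3 probes stood at 61.0%, 61.6% and 69.2% of wild type with a wider spread, and the exact tests gave p = 0.115, 0.126 and 0.188. There 1, 3 and 3 of the 6 heterozygous arrays lay below all wild-type arrays. Heterozygous cocaine array 23 lay at 9.22 in the last probe, above every wild-type cocaine array (highest 8.94). Foxp2 thus separated the genotype labels of the saline arrays but not those of the cocaine arrays. The other Foxp2 probe was detected on 0 arrays. Whether a probe overlaps the mutated base was not analysed here. Over all probes limma did not call Foxp2 for genotype: averaged over both injections it differed by -0.51 ± 0.19 (log2, SE; 95% interval -0.90 to -0.12; adjusted p = 1.00). Between cocaine and saline arrays Foxp2 differed by -0.65 ± 0.19, which did not pass (adjusted p = 0.0520), and by 0.02 ± 0.15 with the striatal marker score and -0.15 ± 0.20 with the excitatory marker score as a covariate. The genotype difference averaged over injections was -0.18 without the 3 arrays described next and -0.17 with the striatal score, where neither passed an unadjusted p of 0.05, and -0.45 with the excitatory score, where it did. With the striatal score the other 2 detected probes differed by -0.29, which passed an unadjusted p of 0.05, and -0.21, which did not. After saline the 3 probes differed by -0.49, -0.42 and -0.38 with the striatal score, and each passed an unadjusted p of 0.05. After cocaine they differed by -0.08, 0.01 and 0.05 with it, and none of them passed an unadjusted p of 0.05.

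**Figure D1:**
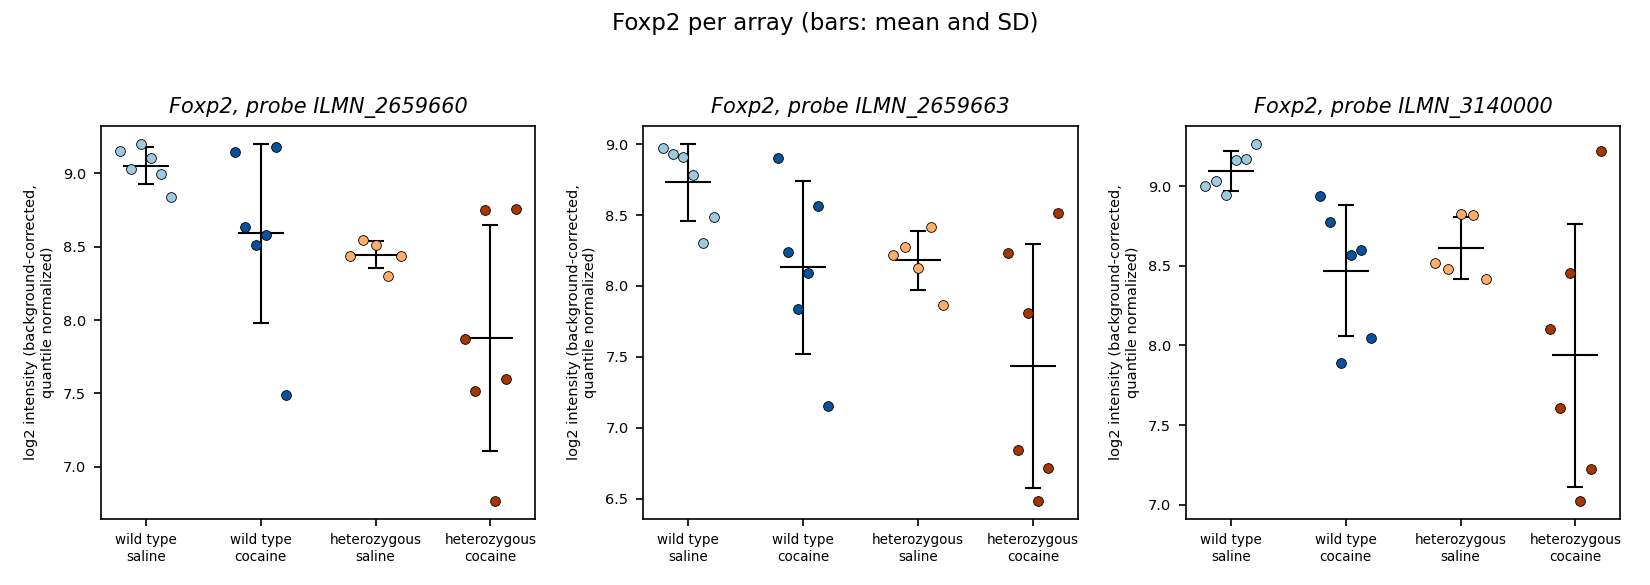
Log2 intensity of the 3 detected Foxp2 probes on each array, by genotype and injection, with group means and SD as bars. After saline the heterozygous means lay at 65.7%, 68.2% and 71.5% of wild type, and after cocaine both genotypes were more spread.

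The levels of cell type markers differed between arrays. Markers of excitatory cortical neurons, which are few inside the striatum, and markers of striatal projection neurons ran in opposite directions across the arrays. The excitatory score, a mean log2 deviation over 9 markers, averaged -0.23 ± 0.26 (SD, n = 6) in wild type after saline and 0.14 ± 0.30 after cocaine (n = 6). In heterozygotes it averaged -0.36 ± 0.41 after saline (n = 5) and 0.39 ± 0.39 after cocaine (n = 6). The striatal score over 15 markers averaged 0.17 ± 0.08 and -0.01 ± 0.12 in wild type, and 0.13 ± 0.07 and -0.26 ± 0.29 in heterozygotes, after saline and cocaine. On the first principal component, with 15.7% of the variance, 3 heterozygous cocaine arrays (numbers 9, 16 and 19) lay between 27.3 and 31.7, and the next array, wild-type cocaine array 24, lay at 18.8. These 3 had excitatory scores of 0.66 to 0.78 and striatal scores of -0.60 to -0.45. They are 3 of the 6 heterozygous cocaine arrays and were picked for their place on this component. Fits without them therefore have fewer arrays, and a call lost there need not be a lost change.

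**Figure D2:**
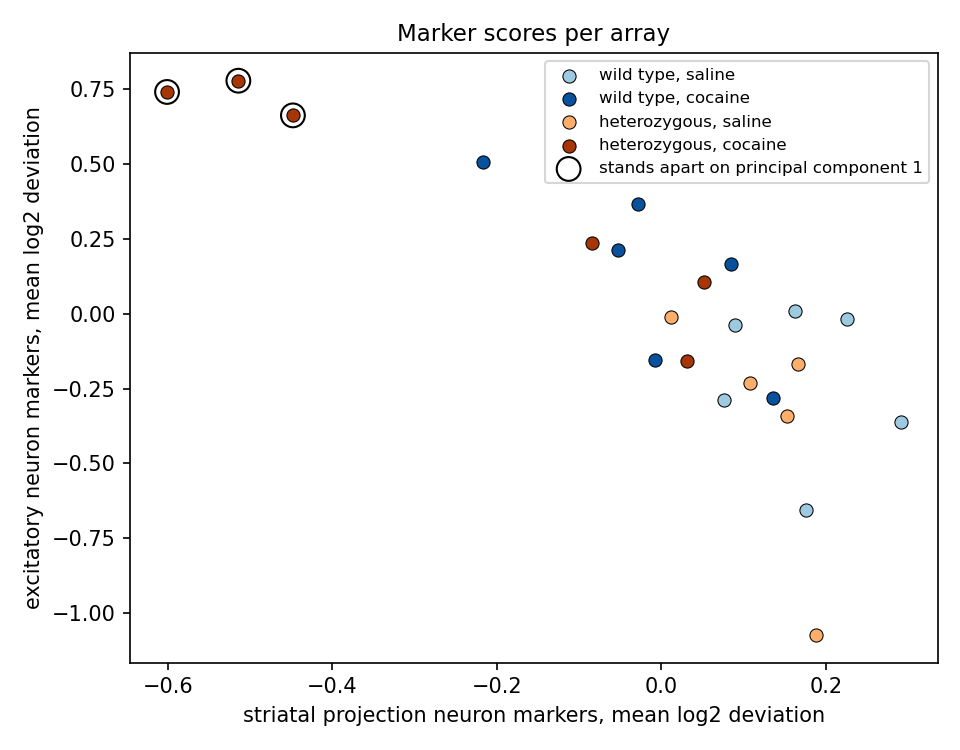
Mean log2 deviation of the excitatory neuron markers (vertical axis) and of the striatal projection neuron markers (horizontal axis), with 1 point per array coloured by group. Rings mark the 3 heterozygous cocaine arrays that stand apart on the first principal component, at excitatory scores of 0.66 to 0.78.

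For cocaine averaged over the genotypes, the 4 genes with the smallest p, Egr2, Arc, Fos and Dusp4, belong to the lists of genes that neurons switch on within minutes of activity. Egr2, a zinc-finger immediate-early transcription factor, rose 3.84-fold (log2 change 1.94 ± 0.18, SE; adjusted p = 3.6e-06; 12 cocaine against 11 saline arrays). Its level went from 8.70 ± 0.34 to 10.6 ± 0.68 in wild type and from 8.55 ± 0.26 to 10.5 ± 0.44 in heterozygotes (log2 intensity, SD), and all 12 cocaine arrays lay above all saline arrays. Fos, a subunit of the AP-1 transcription factor, rose 2.71-fold (1.44 ± 0.16; adjusted p = 2.5e-05; 11 of 12 arrays above all saline arrays). Arc, which controls the endocytosis of AMPA receptors at synapses, rose 2.25-fold (1.17 ± 0.12; adjusted p = 8.5e-06; 12 of 12). In all, limma called 451 of the 10138 genes, 320 higher and 131 lower after cocaine, and 22 of them changed by over 1 log2 unit.

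**Figure D3:**
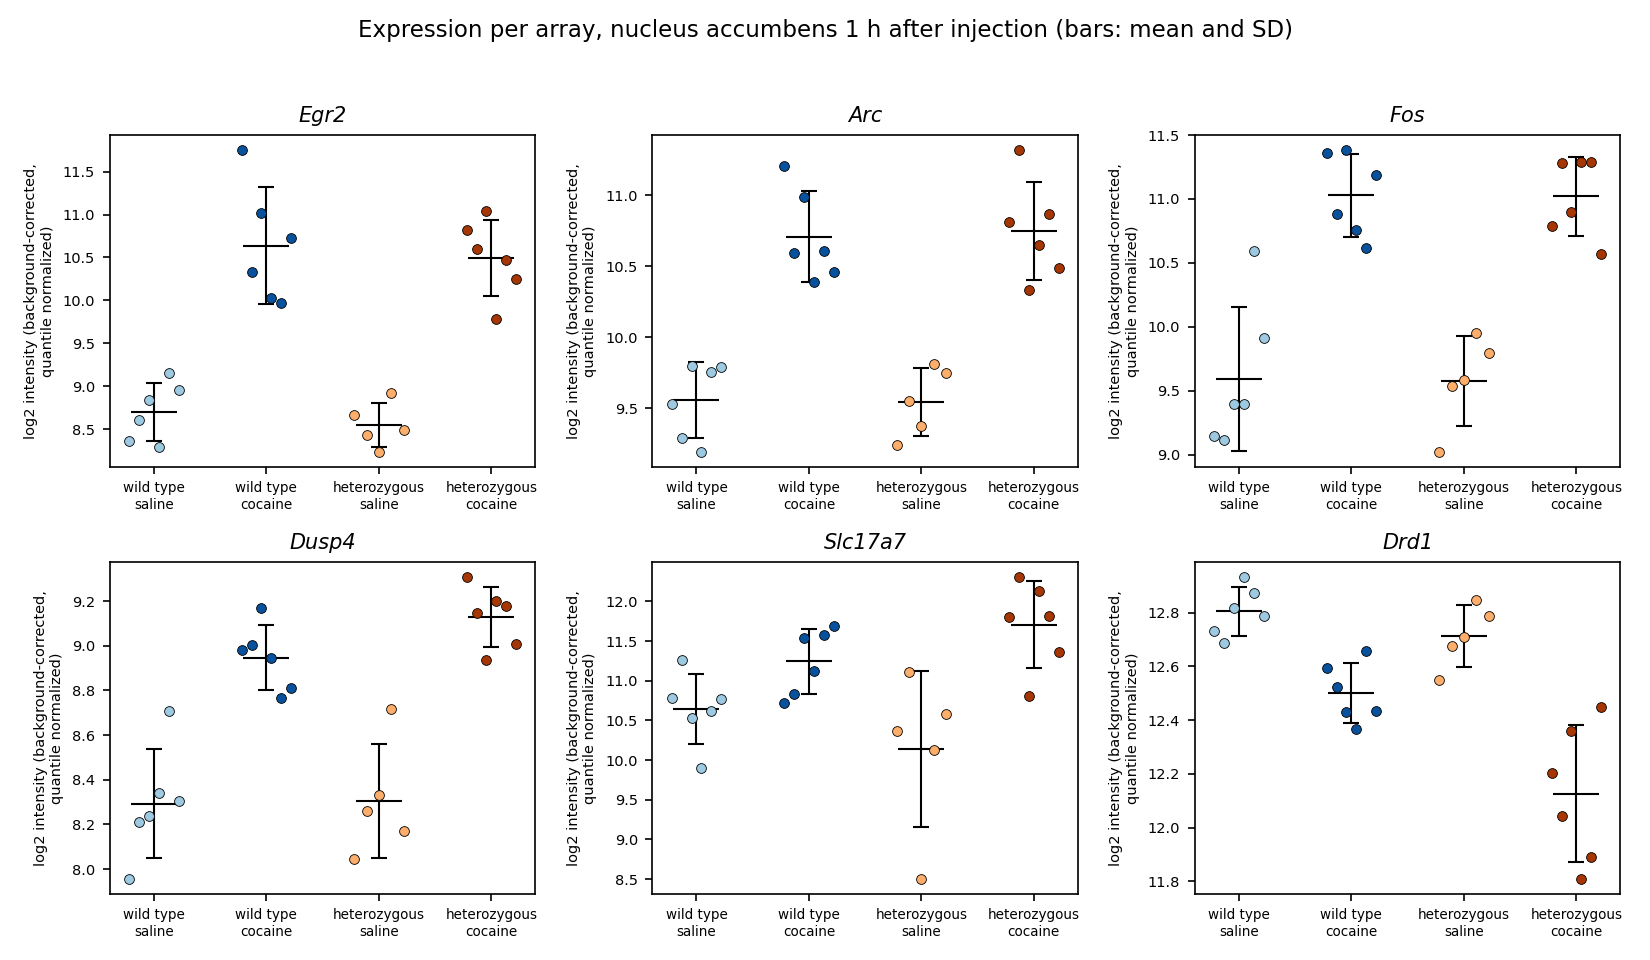
Log2 intensity of Egr2, Arc, Fos, Dusp4, Slc17a7 and Drd1 on each array, by genotype and injection, with group means and SD as bars. All 12 cocaine arrays lay above all 11 saline arrays for Egr2, Arc and Dusp4, and Slc17a7 and Drd1 were more spread in the heterozygous groups.

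Of the 19 immediate-early transcription factors measured, 12 rose and 0 fell, and 7 did not pass (13 higher and 1 lower adjusted over the list alone; median change 0.47). Beside Egr2 and Fos these included Egr4 (0.76 ± 0.10), Fosl2 (0.74 ± 0.10) and Egr1 (0.45 ± 0.06). Npas4, an activity-dependent transcription factor of neurons, rose by 0.99 ± 0.13 and was higher on 12 of 12 arrays. Of the 21 activity-regulated effector genes, 9 rose and 0 fell (12 higher adjusted over the list alone). Arc was joined by the neurotrophin gene Bdnf (1.45 ± 0.23), by Nrn1, which encodes the neurite-promoting protein neuritin (1.22 ± 0.23), and by the matricellular gene Ccn1. Bdnf and Nrn1 were lowest in their groups on heterozygous saline array 14 and heterozygous cocaine array 11, as was the excitatory neuron gene Slc17a7. With the excitatory score as a covariate Bdnf (0.53 ± 0.13; adjusted p = 0.231) and Nrn1 (0.34 ± 0.16; adjusted p = 1.00) did not pass, and without the 3 arrays that stood apart Bdnf passed (1.20 ± 0.25) and Nrn1 did not (1.00 ± 0.25; adjusted p = 0.092). Ccn1 was not detected on any saline array and was at least 1.13-fold higher after cocaine (adjusted p = 0.0015). Among the 8 MAP kinase feedback genes measured 4 rose and 0 fell (6 higher adjusted over the list alone). These were the phosphatase genes Dusp4 (0.74 ± 0.08), Dusp1 (0.60 ± 0.08), Dusp6 (0.56 ± 0.08) and Dusp5 (0.43 ± 0.09), of which Dusp5 did not pass without the 3 arrays (0.40 ± 0.10; adjusted p = 0.0789). The camera tests, two-sided, of these 3 lists gave adjusted p = 9.9e-17, 2.4e-10 and 1.6e-07, and adjusted p = 0.00453, 0.00547 and 0.00547 with an estimated correlation. Without the 3 arrays that stood apart the same tests gave adjusted p = 2.5e-20, 1.9e-12 and 8.1e-09.

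Genes of excitatory neurons were higher on the cocaine arrays. Of 9 excitatory cortical markers 4 rose and 0 fell (6 higher adjusted over the list alone; median 0.48). Neurod2 and Tbr1, transcription factors of cortical excitatory neurons, rose by 1.18 ± 0.23 and 0.97 ± 0.26. Slc17a7 and Slc17a6, vesicular glutamate transporters, rose by 1.09 ± 0.24 and 0.48 ± 0.13. The camera test gave an adjusted p of 2.3e-05, and adjusted p = 0.110 with an estimated correlation. The median of the list was 0.34 without the 3 arrays. Of the named genes outside the fixed lists, Adcyap1, which encodes the neuropeptide PACAP, rose by 1.63 ± 0.28 and the neuromedin B receptor gene Nmbr by 1.54 ± 0.29. The secreted-protein gene Tafa1 was called higher (adjusted p = 0.00015) and was detected on 2 of 11 saline arrays, so no size is given. Ly6g6e (1.40 ± 0.27), the guanylate cyclase gene Gucy2g (1.32 ± 0.22) and the synaptic zinc transporter gene Slc30a3 (1.27 ± 0.25) followed. Arsj was not detected on any saline array and was at least 1.21-fold higher. Among 13 neuropeptide and opioid receptor genes 3 rose and 1 fell (5 and 5 adjusted over the list alone). The peptide genes Cck (1.24 ± 0.22), Vip (1.13 ± 0.22) and Npy (0.26 ± 0.07) were higher. Of 10 striatal interneuron markers 2 rose, Vip and Npy (5 higher and 3 lower adjusted over the list alone). Of 11 genes linked to Foxp2 in earlier reports Nrn1, Cck and Mef2c (0.49 ± 0.09) rose (3 higher and 2 lower adjusted over the list alone). With blocks of array numbers Tbr1 (0.99 ± 0.30; adjusted p = 0.0777) and Npy (0.23 ± 0.07; 0.102) did not pass. Without the 3 arrays Neurod2, Tbr1, Slc17a7, Slc17a6, Nmbr, Ly6g6e, Slc30a3, Cck, Vip, Npy and Mef2c did not pass, and Adcyap1, Tafa1, Gucy2g and Arsj did.

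Genes of striatal neurons were lower on the cocaine arrays. Of 15 striatal projection neuron markers 6 fell and 0 rose (12 lower adjusted over the list alone; median -0.30). They included the retinoic acid receptor gene Rarb (-0.47 ± 0.11), the G-protein regulator gene Rgs9 (-0.42 ± 0.10), the dopamine-regulated phosphatase inhibitor gene Ppp1r1b (-0.40 ± 0.09) and Rasd2 (-0.36 ± 0.09). Of 6 markers of D2 medium spiny neurons 4 fell (4 adjusted over the list alone), namely P2ry1 (-0.55 ± 0.15), Gpr6 (-0.54 ± 0.12), the enkephalin precursor gene Penk (-0.53 ± 0.13) and the dopamine receptor gene Drd2 (-0.47 ± 0.13). Of 7 markers of D1 medium spiny neurons the dopamine receptor gene Drd1 (-0.45 ± 0.07) and Slc35d3 (-0.42 ± 0.10) fell (4 lower and 1 higher adjusted over the list alone). Camera gave adjusted p = 1.8e-09, 0.00076 and 0.0019 for these lists, and adjusted p = 0.126, 0.126 and 0.146 with an estimated correlation. The larger decreases outside the lists were of Musk, a receptor tyrosine kinase (-0.70 ± 0.10), the retinol transporter gene Stra6 (-0.68 ± 0.16), Irak3, an inhibitor of Toll-like receptor signalling (-0.63 ± 0.12), Serpina9 (-0.62 ± 0.11), the transcription factor gene Onecut2 (-0.60 ± 0.12) and the protein kinase C gene Prkch (-0.60 ± 0.14). Striatal scores were lower on the cocaine arrays, as given above. Without the 3 arrays Drd1 (-0.34 ± 0.06), Musk (-0.58 ± 0.10) and Onecut2 (-0.68 ± 0.13) passed. The other 13 genes given here did not, among them Drd2 (-0.30 ± 0.12; adjusted p = 0.37) and Penk (-0.33 ± 0.11; adjusted p = 0.23). With blocks of array numbers Rgs9 (-0.39 ± 0.11; adjusted p = 0.0505), P2ry1 (-0.59 ± 0.17; 0.0665), Rasd2 (-0.28 ± 0.08; 0.0746) and Drd2 (-0.44 ± 0.13; 0.0759) did not pass.

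Few genes of the other lists changed. Of 24 glucocorticoid-responsive genes 3 rose, Dusp1, the clock gene Per1 (0.40 ± 0.10) and Cebpb (0.34 ± 0.07), and of 13 circadian clock genes Per1 and Bhlhe40 (0.47 ± 0.08) rose (3 and 2 adjusted over the list alone). Of 13 dopamine, glutamate and GABA receptor genes Drd1 and Drd2 fell (3 lower adjusted over the list alone). Of 3 measured choroid plexus and ependyma markers Kl fell (-0.46 ± 0.12; 2 lower adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.126 with an estimated correlation). Kl did not pass with blocks of array numbers (-0.39 ± 0.14; adjusted p = 0.126), and without the 3 arrays Kl, Per1 and Cebpb did not. The 19 genes of the mitochondrial respiratory chain held 0 called genes and a median of 0.07 (camera adjusted p = 0.011, and adjusted p = 0.146 with an estimated correlation). The remaining 11 lists held 0 called genes by limma, with medians between -0.17 and 0.29 and camera adjusted p of 0.125 or more. They were heat shock proteins, endoplasmic reticulum stress genes (1 higher adjusted over the list alone), the FOXP family (2 lower), sex-linked genes, and markers of septal neurons, astrocytes, oligodendrocytes, their precursors, microglia (2 lower), endothelial cells and blood cells. Median and mean differed in sign for the glucocorticoid, heat shock, neuropeptide, Foxp2-linked, sex-linked and astrocyte lists.

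The count of 451 genes moved with single arrays. It fell to 255 and 287 without heterozygous saline arrays 14 and 18, to 259, 270 and 299 without heterozygous cocaine arrays 9, 16 and 19, and to 266 without wild-type cocaine array 24, and it rose to 694 without heterozygous cocaine array 11. It was 49 without arrays 9, 16 and 19 together, all 49 of them among the 451, and 10 with the excitatory marker score as a covariate, where Egr2 (2.06 ± 0.25), Fos (1.27 ± 0.21), Arc (1.05 ± 0.16), Egr4, Dusp4 and Dusp1 were among the genes that passed. Of the 49 named genes called here 19 passed without the 3 arrays and 30 did not, and with the excitatory score 6 passed, 42 did not and 1, Tbr1, changed sign. With blocks of array numbers 42 of the 49 passed. Without a filter Drd2, Kl, P2ry1, Slc17a6 and Tbr1 did not pass, with the replicate block in the authors' values Kl, Npy and Tbr1 did not, under quantile normalization P2ry1 did not and with an intensity trend Tbr1 did not.

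In wild type alone 11 genes rose and 0 fell, by limma. They were Egr2 (3.83-fold; 1.94 ± 0.25; adjusted p = 0.0013), Fos (1.44 ± 0.22), Arc (1.15 ± 0.16), Fosb, another AP-1 subunit (0.93 ± 0.18), Egr4 (0.84 ± 0.14), Fosl2 (0.77 ± 0.13), Dusp4 (0.65 ± 0.12), Midn (0.57 ± 0.09), Dusp1 (0.56 ± 0.11), Frmd6 (0.55 ± 0.10) and Egr1 (0.43 ± 0.08), over 6 against 6 arrays. Fosb was above all saline arrays on 5 of 6 cocaine arrays and the others on 6 of 6. At an unadjusted p under 0.05 there were 870 genes. The immediate-early list held 6 called genes, the effector list 1 and the MAP kinase list 2 (11, 7 and 4 adjusted over the list alone), and their camera calls held with an estimated correlation (adjusted p = 0.00329, 0.0206 and 0.00979). Excitatory markers (median 0.41; camera adjusted p = 0.00455) and striatal projection markers (median -0.17; 6.0e-05) moved as lists with 0 called members, and adjusted p = 0.290 and 0.311 with an estimated correlation. The interneuron markers (median 0.12) had adjusted p = 0.012, and adjusted p = 0.0364 with an estimated correlation. Glucocorticoid-responsive genes (median 0.11; 1 called, Dusp1; adjusted p = 0.027), the respiratory chain (0.05; 0.018) and oligodendrocyte markers (0.07; 0.041) were higher as lists, and adjusted p = 0.295, 0.290 and 0.346 with an estimated correlation. The count was 5 without wild-type saline array 2 or 7 or wild-type cocaine array 4, 6 without wild-type saline array 5 or wild-type cocaine array 12 or 24, 7 without wild-type saline array 15, and 2 in a fit of these groups alone. It was 6 without the 3 arrays that stood apart and 7 with the excitatory score as a covariate. Dusp1 (0.54 ± 0.11) and Fosb (0.91 ± 0.19) did not pass with blocks of array numbers (adjusted p = 0.143 for both), without a filter or under quantile normalization. Oligodendrocyte markers had adjusted p = 0.105 with these blocks.

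In heterozygotes 198 genes rose and 74 fell, over 6 against 5 arrays, and 57 changed by over 1 log2 unit. Egr2 rose 3.85-fold (1.95 ± 0.26; adjusted p = 0.00081), Fos 2.71-fold (1.44 ± 0.23) and Arc 2.30-fold (1.20 ± 0.17), each on 6 of 6 cocaine arrays above all saline arrays. Tafa1 was not detected on any saline array of heterozygotes and was at least 2.99-fold higher (adjusted p = 0.00057). Adcyap1 rose by 2.30 ± 0.40, Nmbr by 2.11 ± 0.42, Ly6g6e by 2.03 ± 0.38, Bdnf by 1.99 ± 0.34, Slc30a3 by 1.97 ± 0.36, Arhgap15, which encodes a Rac GTPase-activating protein, by 1.84 ± 0.32 and Nrn1 by 1.75 ± 0.34. The Notch-pathway gene Dlk1 (-1.06 ± 0.27), the homeobox gene Gbx2 (-1.02 ± 0.24), Zbtb7c (-0.91 ± 0.19), the choline transporter gene Slc5a7 (-0.91 ± 0.22), Stra6 (-0.89 ± 0.24), C1ql2 (-0.86 ± 0.23), Musk (-0.86 ± 0.15), Ecel1 (-0.85 ± 0.23) and Penk (-0.81 ± 0.18) fell. The imprinted gene Peg10 was at least 1.05-fold lower. Of the 44 named genes called in heterozygotes 35 passed with blocks of array numbers, where Stra6, Ecel1 and Slc5a7 did not (adjusted p = 0.059, 0.0598 and 0.0627). Under quantile normalization 35 passed, without a filter 27 and in a fit of these groups alone 19. Without the 3 arrays that stood apart, which left fewer heterozygous cocaine arrays, 1 of the 44 passed, and with the excitatory score 0 did.

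In the lists, 8 immediate-early, 6 effector and 3 MAP kinase genes rose in heterozygotes (13, 9 and 3 adjusted over the list alone; camera adjusted p = 0.0176, 0.0176 and 0.018 with an estimated correlation). Excitatory markers rose in 4 of 9 cases, with Slc17a7 at 1.57 ± 0.34. Markers of D2 neurons fell in 3 of 6, of striatal projection neurons in 2 of 15 and of D1 neurons in 1 of 7 (6 higher, and 5, 12 and 5 lower, adjusted over the list alone). Camera gave adjusted p = 5.1e-05, 0.00028, 3.6e-09 and 0.00052 for these 4 lists, and adjusted p = 0.107 for each with an estimated correlation. Septal markers (median -0.37; 1 lower), choroid plexus markers (-0.58; 1 lower) and endothelial markers (0.11; 0 called) had adjusted p = 0.039, 0.0098 and 0.034, and adjusted p = 0.203, 0.107 and 0.266 with an estimated correlation. With blocks of array numbers septal markers had adjusted p = 0.0765. Excitatory scores were higher and striatal scores lower on these cocaine arrays, as given above. The 272 calls fell to 67 and 95 without heterozygous saline arrays 14 and 18, to 91, 97 and 121 without heterozygous cocaine arrays 9, 16 and 19, to 85 with the replicate number as a block in the authors' values and to 48 in a fit of these groups alone, and rose to 521 without array 11. Without arrays 9, 16 and 19 together 1 gene passed, Egr2 (2.16 ± 0.31; adjusted p = 0.019), and with the excitatory score as a covariate 0 did (406 at an unadjusted p under 0.05).

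Whether the response to cocaine depended on genotype was tested as an interaction, and limma called 0 genes (488 at an unadjusted p under 0.05). In the simulated data 17 of 100 interaction differences of 0.5 log2 units and 87 of 100 of 1 log2 unit were recovered. Differences near 0.5 log2 units would thus mostly be missed. The simulated noise was independent between probes and had the same spread in all 4 groups. The real arrays share structure and differ in spread between groups, so differences of 1 log2 unit may also be missed more often than in the simulation. Among the activity genes, Egr2 differed between heterozygotes and wild type by 0.01 (95% interval -0.74 to 0.76), Fos by 0.00 (-0.65 to 0.66) and Arc by 0.05 (-0.44 to 0.54). Over the 25 activity genes called for cocaine the median change was 0.61 in wild type and 0.69 in heterozygotes. Bdnf (1.09; interval 0.13 to 2.05) and Nrn1 (1.06; interval 0.10 to 2.02) were the 2 of these 25 with an unadjusted p under 0.05, and both had an adjusted p of 0.927. Fosb differed by -0.49 (-1.03 to 0.05), Nr4a2, an orphan nuclear receptor, by 0.63 (-0.24 to 1.5) and Dusp5 by -0.33 (-0.70 to 0.04). The 3 genes with the smallest p were Slc17a8 (-0.78 ± 0.18), Smyd5 (-0.57 ± 0.14) and Tafa1, with adjusted p = 0.927. Tafa1 was undetected on all heterozygous saline arrays, so no size of its difference is given. Of the 11 genes called in wild type 9 were also called in heterozygotes, where 0.295 is the overlap of independent lists. Of the 272 genes called in heterozygotes 254 (93.4%) had the same sign in wild type, with medians of 0.70 in heterozygotes and 0.34 in wild type for the higher genes and -0.60 and -0.17 for the lower genes. These genes were picked by their change in heterozygotes. As lists, D1 neuron markers (median -0.28), D2 neuron markers (-0.39), striatal projection markers (-0.19) and septal markers (-0.60) were lower in the interaction by camera (adjusted p = 0.036, 0.036, 0.013 and 0.013, and adjusted p = 0.417 for each with an estimated correlation), with 0 called members. Without arrays 9, 16 and 19 these became 0.983, 0.823, 0.306 with the opposite sign, and 0.107.

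**Figure D4:**
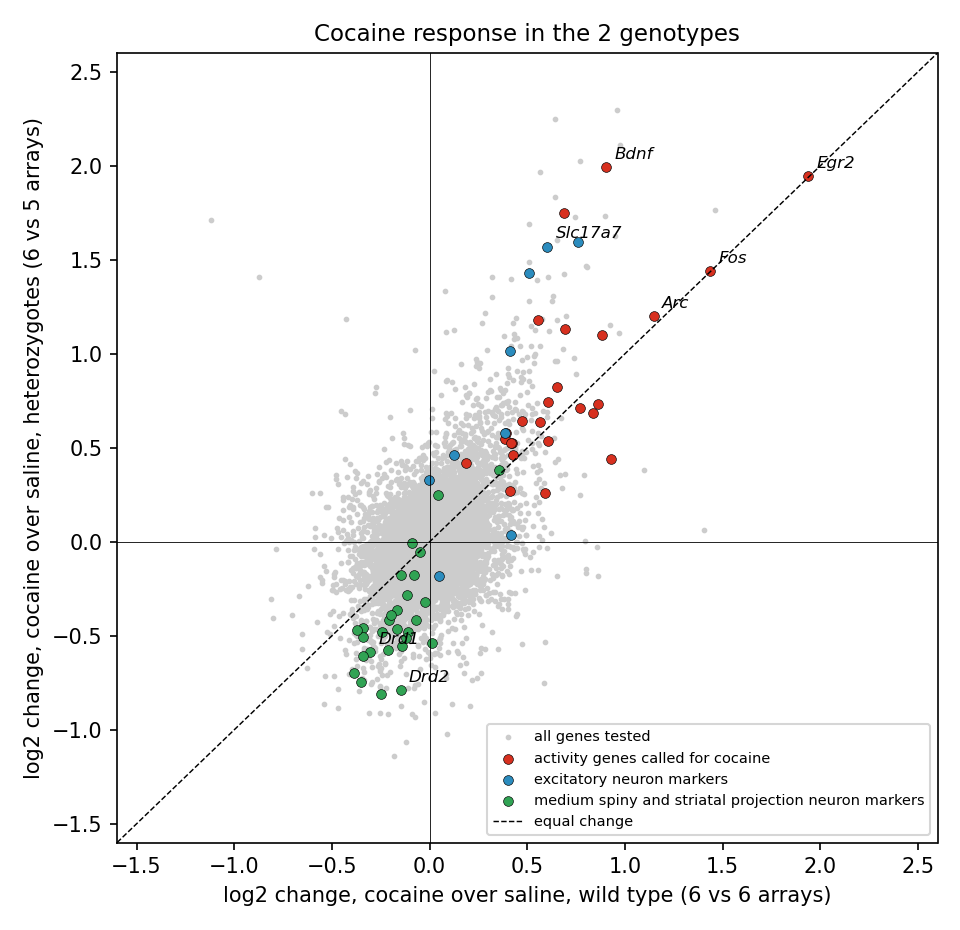
Log2 change after cocaine in wild type (horizontal axis, 6 against 6 arrays) and in heterozygotes (vertical axis, 6 against 5 arrays), with 1 point per gene, the 25 called activity genes, the excitatory and the striatal markers coloured, and a dashed line of equal change. Egr2, Fos and Arc lie close to the line, and Bdnf lies at 0.90 in wild type and 1.99 in heterozygotes.

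Between the genotypes limma called 0 genes averaged over both injections, 0 after saline and 0 after cocaine (480, 376 and 674 at an unadjusted p under 0.05). The smallest p averaged over both were those of Vps37d, an endosomal sorting gene (0.30 ± 0.06), the autophagy protease gene Atg4d (0.40 ± 0.09) and the integrin gene Itga11 (-0.37 ± 0.08), all with adjusted p = 0.523. After saline they were those of Tmem63a (0.37 ± 0.10), Prkd1 (-0.39 ± 0.10) and the Wnt receptor gene Fzd10 (0.64 ± 0.17), with adjusted p = 0.999. After cocaine they were those of the synaptic scaffold gene Homer2 (0.65 ± 0.14; 6 of 6 heterozygous arrays above all wild-type arrays), Tmem41a (-0.32 ± 0.07) and the glutamate transporter gene Slc17a8 (-0.52 ± 0.12), with adjusted p = 0.538, 0.538 and 0.576. Of the relatives of Foxp2, Foxp1 differed by -0.06 ± 0.14 and Foxp4 by 0.16 ± 0.07, averaged over both injections, with adjusted p = 1.00. Striatal projection markers (median -0.14; adjusted p = 2.8e-07) and D2 neuron markers (-0.15; 0.023) were lower in heterozygotes as lists, and adjusted p = 0.611 for both with an estimated correlation. After saline septal markers were higher (0.34; adjusted p = 0.022) and endothelial markers lower (-0.12; 0.022), and adjusted p = 0.345 and 0.450 with an estimated correlation. After cocaine markers of D1 neurons (-0.32), D2 neurons (-0.36), striatal projection neurons (-0.24) and oligodendrocytes (-0.15) were lower (adjusted p = 0.0047, 0.0014, 4.8e-08 and 0.016, and 0.328, 0.328, 0.328 and 0.393 as adjusted p with an estimated correlation). Without arrays 9, 16 and 19 the D1 and striatal projection lists had the opposite sign after cocaine (adjusted p = 0.996 for both), and D2 markers had adjusted p = 0.850. In a fit of the saline groups alone 1 gene, Prrt4, named after its value was seen, passed (-1.05 ± 0.13; adjusted p = 0.0347).

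Sex differences were tested in the authors' processed values, which carry the animals' labels, over 9274 genes in 12 female and 11 male animals. Called by limma were 118 genes higher and 51 lower in females, each by under 1 log2 unit. Setd4, a methyltransferase gene (0.82 ± 0.13; adjusted p = 0.0044), Gm5820 (0.93 ± 0.11; 0.00062), the carboxypeptidase gene Agbl5 (0.65 ± 0.12), the tyrosine kinase gene Bmx (0.64 ± 0.13), Zcwpw1 (0.64 ± 0.12) and the protocadherin gene Pcdhb3 (0.55 ± 0.08) were higher in females. Cyb5d2 (-0.62 ± 0.16), the respiratory chain gene Ndufb11 (-0.52 ± 0.10), the kinase genes Mapk4 (-0.52 ± 0.11) and Prkce (-0.44 ± 0.10) and the transcription factor gene Pou3f1 (-0.51 ± 0.13) were lower. Xist and the Y-linked genes have no value in the authors' processed table. In the raw intensities 4 heterozygous cocaine arrays had Xist detected against 3 females in the labels, and in the other 3 groups the counts matched. The fits of sex used the labels as given. The arrays with the Y-linked gene Eif2s3y detected were numbers 1 to 7, 9, 10 and 12, and those with Xist were number 11 and numbers 13 to 24. Sex and a batch by array number therefore cannot be told apart in the genes called for sex. The count of 169 fell to 50, 95 and 89 without replicate 1 of the heterozygous saline, wild-type saline and heterozygous cocaine groups, to 106 and 102 without heterozygous cocaine replicates 4 and 5, to 106 without wild-type saline replicate 6, to 105 without wild-type cocaine replicate 6 and to 110 without heterozygous saline replicate 5, and rose to 299 without wild-type cocaine replicate 5. With the replicate number as a block 0 genes passed (544 at an unadjusted p under 0.05), and number 3 alone held both sexes. Whether cocaine acted differently in the sexes was tested as an interaction, where limma called 0 genes (604 at an unadjusted p under 0.05). In the simulated data 18 of 100 such differences of 0.5 log2 units and 72 of 100 of 1 log2 unit were recovered, with the same limits of the simulation as for the interaction of genotype and cocaine. The smallest p were those of Srrd (-0.62 ± 0.14, females minus males), Serinc5 (-0.72 ± 0.17) and Smim27 (-0.45 ± 0.11), with adjusted p = 0.71.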

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

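The tests of array-number blocks, of the interaction as an account of the counts and of the sex labels were chosen after the result was seen. The fits with the excitatory marker score and without the 3 arrays that stand apart are alternatives added after the data were seen, although what they would show was written before they were run.

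The first pattern is that excitatory neuron genes were higher and striatal genes lower on the cocaine arrays. RNA of neighbouring excitatory neurons in some punches may account for it: of 422 called genes outside the activity lists and the marker list, 80.6% had, across the 11 saline arrays alone, a slope on the excitatory score with the sign of their cocaine change. These saline arrays were also part of the fit that called the genes. Heterozygous saline array 14, with the lowest score (-1.07), weighs most in the slopes. The median of 100 shuffles of the score was 49.8%, but 1 shuffle reached the same share, so under the rule written beforehand the test did not settle it. A batch by array number is argued against, since the median change of the excitatory markers was 108% of its size in the fit with blocks of array numbers (0.52 against 0.48). Without the 3 arrays that stand apart the median was 71.2% of its size (0.34). These are cocaine arrays with the highest excitatory scores of all (0.66 to 0.78), so leaving them out would lower the median whatever the cause. The fall therefore does not tell how much of the pattern is particular to them, and a change of 0.34 remained in the other arrays. A change of these genes by cocaine itself stays open, as untested.

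The second pattern is that 272 genes were called for cocaine in heterozygotes and 11 in wild type. With the excitatory marker score as a covariate 0 genes passed in heterozygotes and 7 in wild type. Unequal amounts of RNA of neighbouring excitatory neurons in the heterozygous punches may account for this. Whether the cocaine or the saline punches were unusual is not settled. The 272 calls fell to 91, 97 and 121 without cocaine arrays 9, 16 and 19. They fell to 67 without heterozygous saline array 14, which had the lowest excitatory score (-1.07). The score differs between the injections, so the covariate also widens the errors, and Egr2 in heterozygotes went from 1.95 ± 0.26 to 2.11 ± 0.35. That the genotype changes the response to cocaine stays open, since limma called 0 genes for the interaction and 962 probes had an unadjusted p under 0.05, with a median of 854 over the splits.

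The last pattern weighed is that 4 heterozygous cocaine arrays had Xist detected and 2 had the Y-linked gene Eif2s3y, against 3 females and 3 males in the labels. A wrong sex label on 1 animal may account for it, since 0 arrays had both genes detected among 13 with Xist, and the counts matched the labels in the other 3 groups. The test written for it counted any Y-linked gene against it, and Uty was detected on 6 of the 13, but 5 of these lie in groups that match their labels and its levels overlap those of the other arrays (5.71 to 7.34 against 6.59 to 7.43), while Kdm5d, like Eif2s3y, was detected on 0. A swap of animals of opposite sex between groups is argued against, since 0 of the 3 other groups lacked an Xist-positive array. The names of the raw columns do not give the animal, and no biological explanation was tested.

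Other splits of the arrays into groups of the same sizes were counted, 100 per comparison with the real one included. For cocaine averaged over genotypes 1 of 100 splits, the real split, gave as many genes (451), and the highest other gave 1. The same held in wild type (11 genes; 1 of 100; highest other 1) and for sex (169 genes; 1 of 100; highest other 0). Chance is thus unlikely for these counts but not excluded, since 1 of 100 is the smallest share the draws can give. The draws were a sample of the possible splits, and a split near the real split could be missed. Of the 272 genes called in heterozygotes, for which chance is not excluded either, 232 are among the 451. For sex the splits do not separate sex from a batch. All arrays with Eif2s3y detected have numbers up to 12, and all with Xist, except number 11, have numbers from 13. The share of intensities below 0 was 24.9% to 26.9% on arrays 13 to 18 and 28.3% or more on the others, so the sex count and a batch by array number cannot be told apart. In heterozygotes 2 of 100 splits, the real one included, gave as many as the real 272. By the rule written beforehand this was too few for chance. The other split called 563 genes, more than the real one, so chance is not excluded for this count. That split was the real one with heterozygous cocaine array 11 moved to the saline side and the saline and cocaine labels exchanged, since group sizes were kept. It is thus close to the real comparison with the sign reversed, and it points to a structure of the arrays. By the number of probes at an unadjusted p under 0.05 chance cannot be excluded for genotype averaged over injections (815; 56 of 100 splits; highest other 2339), after saline (785; 54; 2026) or after cocaine (1126; 30; 2569). The same holds for the interaction of genotype and cocaine (962; 41; 2548) and of sex and cocaine (1068; 25; 2157). Some splits gave far more probes than the real one, which points to a structure of the arrays other than the groups.

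Single arrays lay far from the others of their group, by the gap to the nearest array as a share of the range of the group. This held in 15 of 424 groups tested (3.54%), where chance gives about 1 in 20. In wild-type saline mice the shares were 0.675 for Dusp5 (array 15), 0.795 for Irak3 (array 20) and 0.686 for the D2 neuron score (array 7). In wild-type cocaine mice they were 0.634 for Ecel1 (array 13), 0.677 for Musk (array 4) and 0.71 for Prkd1 (array 24). In heterozygous saline mice they were 0.738 for Itga11 (array 1), 0.717 for Npy (array 18), 0.802 for Stra6 (array 22) and, on array 14, 0.753 for Nrn1, 0.778 for the effector gene score and 0.778 for the FOXP family score. In heterozygous cocaine mice they were 0.820 for Nrgn and 0.629 for Nrn1 (array 11) and 0.641 for the oligodendrocyte score (array 3). A difference between genotypes in the response to cocaine was called by camera for markers of D1 neurons (median -0.28), D2 neurons (-0.39), striatal projection neurons (-0.19) and septal neurons (-0.60), and for none of them with an estimated correlation (adjusted p = 0.417).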

How the results depend on the processing

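The blocks of array numbers, the excitatory and striatal marker scores as covariates, the fits without the 3 arrays that stand apart and the authors' values without sex were tests chosen after the data were seen, and the others were planned. The count for cocaine averaged over genotypes (451) stayed within 1.5 times its size between 304 and 633 genes under quantile normalization, an offset of 50, the authors' values with and without sex, detection on all arrays, the replicate block, array weights, an intensity trend and array-number blocks. Over the same alternatives the wild-type count (11) lay between 8 and 13, and that in heterozygotes (272) between 215 and 390, except with the replicate block, where it was 85. The counts for genotype and for both interactions were 0 by limma under every alternative run except the saline groups fitted alone, which gave 1 gene.

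Without a filter the cocaine count was 276 averaged over genotypes and 134 in heterozygotes, with more probes in the adjustment. With the compared groups alone it was 2 in wild type and 48 in heterozygotes, with fewer arrays for the spread and with the spread of those groups only. Spreads differed between groups (SD of the striatal score 0.07 in heterozygous saline and 0.29 in heterozygous cocaine mice). Which of these mattered was not tested. With all tested probes counted the cocaine count was 716 averaged and 411 in heterozygotes, and the sex count was 310, since a gene can have several probes. In males alone the counts were 6 averaged, 2 in wild type and 0 in heterozygotes (523 at an unadjusted p under 0.05), and in females alone 113, 0 (448) and 0 (1330). Both fits have fewer animals, with 2 males against 3 females in heterozygous saline mice and 3 of each sex in the other groups. Limma called 0 genes for the interaction of sex and cocaine, and what accounts for 6 against 113 genes in the single-sex fits was not tested. These fits used the sex labels as given, of which 1 in the heterozygous cocaine group is in doubt. With the excitatory score the cocaine counts were 10, 7 and 0 (406), and without the 3 arrays 49, 6 and 1. The wild-type count fell in the latter fit although all wild-type arrays were kept. The sex count (169) was 271 with array weights, 293 with an intensity trend and 0 with the replicate block (544 at an unadjusted p under 0.05). The block leaves number 3 alone to compare the sexes, and Dph5 reversed to -0.29 there. Deviations of arrays with the same number correlated with a mean of 0.07 (-0.26 to 0.42 over 33 pairs), and 13 pairs exceeded 0.1. For arrays with other numbers the mean was -0.01, and 0.05 where the sex label was the same. These small differences do not tell whether the numbers pair the animals. For the other alternatives the cause was not tested.

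Leaving out single arrays gave 255 (heterozygous saline array 14) to 694 (heterozygous cocaine array 11) genes averaged over genotypes, 5 (wild-type saline array 2) to 13 (wild-type cocaine array 13) in wild type, 67 (heterozygous saline array 14) to 521 (heterozygous cocaine array 11) in heterozygotes, and 50 (heterozygous saline replicate 1) to 299 (wild-type cocaine replicate 5) between the sexes. The report names the other arrays that moved a count by over 1.5 times. Foxp2 in the genotype comparison (-0.51) was -0.64 to -0.42 in these fits. It no longer passed an unadjusted p of 0.05 in females alone (-0.58), without the 3 arrays (-0.18) and with the striatal score (-0.17).

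Of 182 list tests 40 were called, and 10 with an estimated correlation, 25 with fry for one direction and 23 with fry for either direction. Without the 3 arrays the D1 and the striatal projection neuron lists reversed for genotype after cocaine (adjusted p = 0.996 for both), as did the striatal projection list for the interaction (0.306). With the excitatory score Tbr1, a member of that score's list, reversed to -0.10 averaged over genotypes and -0.022 in heterozygotes. The slide block was not run, since no slide is named. Normalization, offset and filter alternatives other than detection on all arrays were not run for the sex comparisons, which use the authors' values, nor were compared groups alone for the averaged comparisons and the interactions.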

Other observations

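Markers of glia and vessels held 0 called genes by limma in each list for cocaine averaged over genotypes. The median change was -0.01 for 9 astrocyte markers, 0.04 for 9 oligodendrocyte markers, -0.02 for 5 markers of their precursors, -0.03 for 9 microglial markers and 0.04 for 9 endothelial and mural markers. By genotype, oligodendrocyte markers had a median of 0.07 in wild type, called by camera (adjusted p = 0.041), and -0.06 in heterozygotes (adjusted p = 0.741). Endothelial and mural markers had 0.03 in wild type (adjusted p = 0.726) and 0.11 in heterozygotes, called by camera (adjusted p = 0.034). With an estimated correlation these calls had adjusted p = 0.346 and 0.266, and the difference between genotypes had camera adjusted p = 0.0766 and 0.0863. The 4 blood cell genes had a median of 0.29 and scores that spread widely within the groups, with an SD of 0.92 in heterozygous cocaine mice and 0.24 in heterozygous saline mice. The 14 heat shock genes (median -0.03) and the 14 endoplasmic reticulum stress genes (-0.04) held 0 called genes as well.

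The immediate-early score separated the injections in both genotypes. It averaged -0.27 ± 0.18 (SD, n = 6) in wild-type and -0.31 ± 0.15 (n = 5) in heterozygous saline mice, and 0.27 ± 0.12 (n = 6) and 0.26 ± 0.07 (n = 6) in the cocaine mice. The lowest cocaine array (0.11) lay above the highest saline array (-0.01). Across genes, which are not independent replicates, the changes in wild type and heterozygotes correlated with r = 0.476 over all genes and r = 0.831 over the 48 activity genes measured.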
